A study of Mus musculus with 2 samples.

How the data were processed

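Gene expression was measured on 2 Affymetrix arrays, each hybridised with biotin-labelled cRNA made from total RNA of mouse bone marrow cells. The cells are described as LSK Flt3- cells of wild-type C57BL6J mice, a marrow fraction defined by the absence of lineage markers and of the Flt3 receptor and by Sca-1 and high c-Kit. This fraction is rich in haematopoietic stem cells. Transcripts bear on this definition only in part. Flt3 RNA was present, at 1390 on the array labelled GFP and 1334 on the array labelled Satb1. Kit, the c-Kit gene, was bright, at 3293 and 3388. The lineage antigen genes Cd3e (40.7 and 7.8), Cd4 (27.3 and 4.9) and Ms4a1 (41.0 and 21.2), named after their values were seen, were low. Itgam, also named afterwards, read 127 and 121. Mpo (18391 and 16452) and Pf4 (19179 and 21045), which do not encode such antigens, were bright on both. Surface protein was not measured here. One array was labelled GFP, the control transduction, and 1 array was labelled Satb1. There was 1 array per group, so no replicate spread, standard error or p-value could be given for any difference, and no paired or leave-one-out fit could be made. How many animals or cultures stood behind each array is not given in the sources used here. The comparison made was the array labelled Satb1 against the array labelled GFP.

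The values used were MAS5 intensities. Per the submitters' processing notes, the authors used MAS5, the Affymetrix algorithm that turns the probe pairs of a probe set into a single intensity on a linear scale. The version and the scaling target are not given in the sources used here. The deposited intensities ran from 0.1 to 39460 on the array labelled GFP and from 0.1 to 38287 on the array labelled Satb1. The mean without the lowest and highest 2% of probe sets was 497 on both arrays, which is what scaling each array to a common trimmed mean leaves. A detection call per probe set was not used here. Array data have no read depth, and the number of arrays limits the precision.

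The table held 45037 probe sets. The platform annotation gave 1 gene symbol to 34945 of them, several to 932 and none to 9160. Symbols were updated through the Entrez gene ID against the gene table of the mouse assembly GRCm38.p6, which matched 34741 of the 34945. Probe sets with several symbols or none were left out of the gene comparisons. Each of the 18193 genes was represented by its probe set with the highest mean log2 intensity over both arrays. No coordinates are given, because the sources used here name no genome build.

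All values were handled on the log2 scale as deposited, with no further normalization. Intensities below 61.7, the median of all values of both arrays, were set to that floor before the difference was taken, because low MAS5 intensities are dominated by noise. A difference from a floored value is a lower bound and is written as "at least". A gene was counted as higher or lower where its floored values differed by at least 2-fold. Of the 18193 genes, 11048 were above the floor on at least 1 array and 10316 on both.

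The choice of floor, threshold, probe set rule, named genes and 30 gene lists was made before the data were examined. The lists held 609 different genes, of which 559 were measured. The genes named are the probe sets of Satb1, the 15 genes with the largest and the 15 with the smallest difference, and up to 4 members per list with the largest absolute difference at 2-fold or more. In a list with no such member, up to 2 members with the largest difference are named. Other list members are given where both of their intensities are among the 10 highest of the list. Genes named outside this rule are marked as chosen after their values were seen. For each list, the median log2 difference was set against the medians of 10000 random lists of the same size, drawn to match the list's mean expression in 20 bins. The percentile describes these 2 arrays and is not a test across samples.

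The spread between probe sets of the same gene was used as the only technical error that 1 array per group allows. It was the within-gene SD of the log2 difference among probe sets above the floor on both arrays. Error that all probe sets of a gene share, such as that of a preparation, cancels in this SD. It is therefore not the error of a difference between the arrays. The scripts were tested on simulated data made from the array labelled GFP. All 200 genes simulated to change 4-fold among 18193 genes, with a log2 SD of 0.2, were counted in the right direction (100% of the raised and 100% of the lowered), and 0 other genes were counted. The changed genes were drawn from those with an intensity over 500 on the array labelled GFP. The simulated SD was below the 0.33 seen between the real arrays, or 0.40 at mean intensities under 200. The simulation therefore checks the scripts and does not give the rate of false counts on the real arrays. A list of genes shifted by 0.3 on the log2 scale lay at percentile 100, and 5 of 100 unshifted lists lay outside the middle 95% of random lists.

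The alternatives tried were quantile normalization, median centring, floors at the 25th and 75th percentile, no floor, a pseudocount in place of the floor, the mean over a gene's probe sets, leaving out probe sets that match several transcripts, keeping only genes whose probe sets differ in the same direction, fold thresholds of 1.5 and 3, and random lists not matched on expression. The probe sets left out as matching several transcripts include those with the suffix _a_at, whose transcripts are of the same gene. Restricting lists to members above the floor, and genes to a mean intensity of at least 500, was added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.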

Results

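To ask which transcripts differ when Satb1 is introduced into mouse marrow cells, RNA of transduced cells described as LSK Flt3- was profiled on 1 array labelled Satb1 and 1 array labelled GFP. Satb1 encodes a nuclear protein that binds AT-rich DNA and organises chromatin. Every difference below has n = 1 per group and no replicate check. Of 45037 probe sets, 22850 (50.7%) lay above the floor intensity of 61.7 on the array labelled GFP and 22171 (49.2%) on the array labelled Satb1.

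The transduced gene was examined first, since it checks the labels. Satb1 transcript was not higher on the array labelled Satb1. The brightest Satb1 probe set (1416008_at) read 1116 on the array labelled GFP and 909 on the array labelled Satb1, a log2 difference of -0.30. A second probe set (1416007_at) read 964 and 908, a difference of -0.09. Another (1436182_at) read 288 and 165, a difference of -0.81. The last 2 probe sets were below the floor on at least 1 array, with intensities of 81.4 and 30.5 for 1439449_at and of 27.8 and 18.5 for 1439315_at. The places of these probe sets in the transcript and the extent of the transduced sequence are not given in the sources used here. A probe set outside the transduced sequence would check nothing, so the arrays are named by their labels throughout and all directions rest on those labels.

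The 2 arrays were closely alike. Among 21336 probe sets above the floor on both arrays, the log2 intensities had a Pearson correlation of 0.986 and a Spearman correlation of 0.982 across probe sets, which are not independent replicates. The median log2 difference of these probe sets was -0.03 and its SD 0.33. The within-gene SD of the log2 difference, between probe sets of 1 gene, fell with intensity. It was 0.35 for probe sets with a mean intensity under 200, 0.28 from 200 to 500, 0.19 from 500 to 2000 and 0.13 over 2000.

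A small set of genes differed by at least 2-fold. On the array labelled Satb1, 30 genes were higher and 95 lower, and 10923 of the 11048 genes above the floor (98.9%) were within 2-fold. At a threshold of 3-fold, 9 genes were higher and 10 lower. Of the genes 2-fold apart, 76% were lower. This split depended on the scaling: after quantile normalization 54 genes were higher and 60 lower, so that 52.6% were lower. All 30 genes counted as higher, and 60 of the 95 counted as lower, were counted again after quantile normalization.

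**Figure D1:**
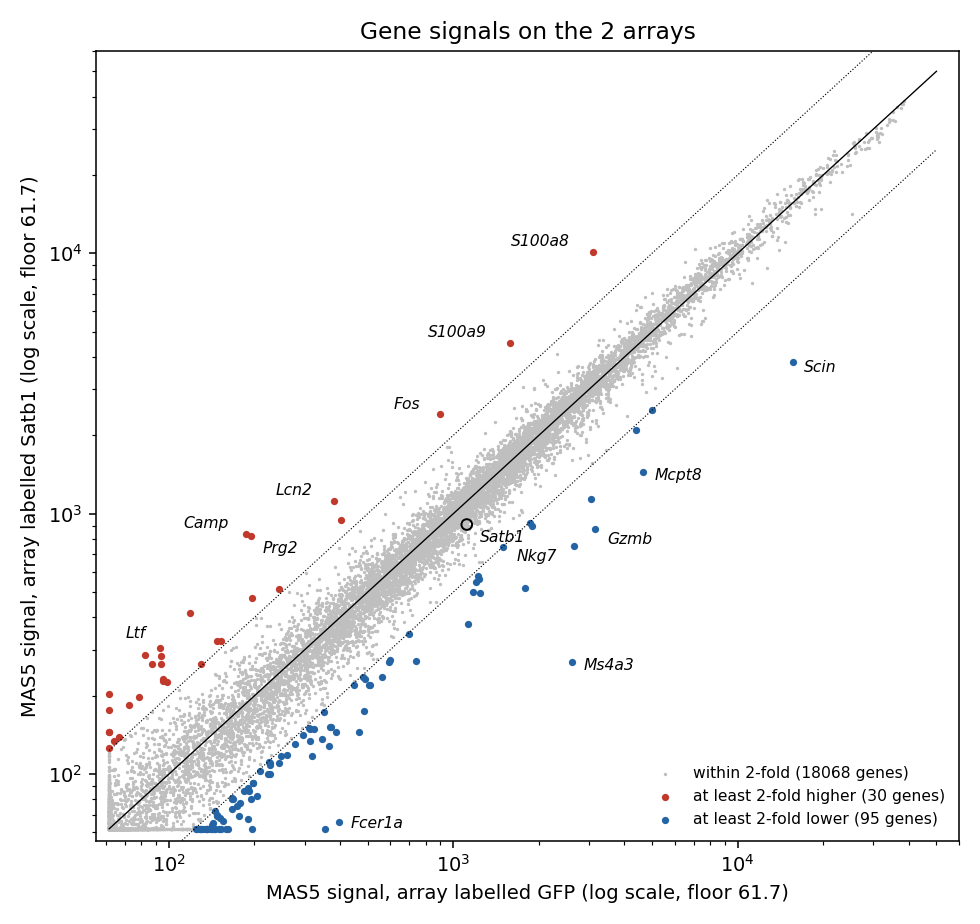
MAS5 intensity of each of 18193 genes on the array labelled GFP (x axis) and the array labelled Satb1 (y axis), both on log scales, with intensities below 61.7 drawn at that floor. The solid line marks equal intensity and the dotted lines 2-fold; 30 genes (red) were at least 2-fold higher and 95 (blue) at least 2-fold lower, and the brightest Satb1 probe set (circle) lay between the lines.

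Of the 15 genes furthest above the control array, 6 belonged to the fixed lists of granulocyte and monocyte genes or of mast cell, basophil and eosinophil genes. Camp, which encodes the antimicrobial peptide cathelicidin, was 4.47-fold higher, at 834 against 187. Prg2, the major basic protein of eosinophil granules, was 4.25-fold higher, at 825 against 194. Ltf, encoding lactoferrin, was 3.28-fold higher (306 against 93.2) and Lcn2, encoding lipocalin 2, 2.95-fold higher (1123 against 381). S100a8 and S100a9, the subunits of calprotectin, were the brightest of these genes. S100a8 read 10109 against 3094, a 3.27-fold difference, and S100a9 read 4539 against 1578, a 2.88-fold difference. The decoy interleukin-1 receptor Il1r2 was 3.50-fold higher, at 416 against 119.

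The other genes among the 15 highest were mostly dim. Fos, which encodes a subunit of the AP-1 transcription factor, read 2406 against 899, a 2.68-fold difference. Btla, an inhibitory lymphocyte receptor, was 3.03-fold higher at 284 against 93.8. Nt5e, the ectonucleotidase CD73, was 2.82-fold higher at 264 against 93.6 by its brightest probe set, with the others below the floor on both arrays. Sgms2, a sphingomyelin synthase, was 3.02-fold higher at 264 against 87.4, with its other probe set below the floor on both arrays. The prostaglandin D synthase gene Hpgds was 2.53-fold higher at 184 against 72.5, and the unnamed transcript 2610316D01Rik 3.50-fold higher at 288 against 82.3. The 2610316D01Rik value comes from a probe set of a kind that can match other transcripts, and its other probe set was below the floor on both arrays. Sdc3, encoding syndecan-3, was at least 3.30-fold higher by its brightest probe set. Another of its probe sets went the other way, at 51.3 against 68.9. The tyrosine kinase gene Yes1 was at least 2.87-fold higher, at 177 against 43.3, by 1 of its 4 probe sets, with the others below the floor on both arrays.

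Of the 15 genes furthest below the control array, 3 belonged to the same lists. Ms4a3, a membrane protein gene of granulocyte and monocyte progenitors, had the largest difference of any gene and was 9.71-fold lower, at 269 against 2609. Fcer1a, the alpha chain of the high-affinity IgE receptor, was 6.07-fold lower at 65.4 against 397. The basophil protease gene Mcpt8 was 3.21-fold lower at 1449 against 4653. Gzmb, encoding granzyme B, was also lower, at 875 against 3162, a 3.61-fold difference, and so was Nkg7, a granule protein gene of NK cells, at 754 against 2667, a 3.54-fold difference.

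The actin-severing protein gene Scin was the brightest gene of this set, at 3827 against 15617, a 4.08-fold difference. Aldh1a1, a retinaldehyde dehydrogenase gene, was at least 5.73-fold lower at 58.1 against 354. Rxra, the retinoid X receptor alpha gene, was at least 3.18-fold lower at 30.2 against 196 by 1 of its 3 probe sets, with the others below the floor. Bpifc was 3.45-fold lower at 519 against 1791, Dnajc6 2.99-fold at 378 against 1131, and the histone H3 gene H3c4 3.22-fold at 145 against 467. Rab26os was 2.79-fold lower at 175 against 487, and 2310015A10Rik 2.84-fold at 67.0 against 190, with its other probe set below the floor on both arrays. The single Rps27 probe set read 272 against 739, a 2.72-fold difference. All measured genes of the ribosomal protein list were far brighter, such as Rplp0 at 26731 against 31338, and their median log2 difference was -0.11. Whether this dim probe set stands for the main Rps27 transcript is therefore not known. The sialyltransferase gene St6galnac3 was 2.85-fold lower at 128 against 365, while another of its probe sets read 202 against 194.

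Gene lists for the blood lineages were then compared. The granulocyte and monocyte list held the most genes 2-fold apart: of 27 measured genes, 5 were higher (Camp, Ltf, S100a8, Lcn2 and S100a9), 2 lower and 20 within 2-fold. The lower ones were Ms4a3 and, named after its value was seen, the G-CSF receptor gene Csf3r, at 494 against 1239 (2.51-fold). Among the bright members within 2-fold, the myeloperoxidase gene Mpo read 16452 against 18391, the proteinase 3 gene Prtn3 12148 against 12209, and the cathepsin G gene Ctsg 8777 against 12716, a log2 difference of -0.53. Lyz2 was higher, at 7280 against 5937. Ngp (1811 against 949), Fcnb (174 against 87.0) and Elane (1320 against 799), named after their values were seen, were higher by under 2-fold. Of the 26 members above the floor, 11 were higher by some amount and 15 lower. Since its members went both ways, the list's median log2 difference was -0.08 and its mean 0.13, and the median lay at percentile 4.42 of matched random lists and at 0.11 of unmatched ones.

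In the mast cell, basophil and eosinophil list, 3 of 17 measured genes were lower, 1 higher and 13 within 2-fold. The lower genes were Fcer1a, Mcpt8 and Ms4a2, the beta chain of the IgE receptor, which read 560 against 1227, a 2.19-fold difference. The higher gene was Prg2. The mast cell carboxypeptidase gene Cpa3 read 5347 against 7418. The median log2 difference was -0.01, at percentile 12.02, with the members below the floor counted at 0. Among the members above the floor it was -0.34, at percentile 0.03 of random lists of genes above the floor, and with the floor at the 25th percentile the median was -0.18, at percentile 1.51.

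By number, few genes of the lymphoid lists were 2-fold apart, but 98.9% of all genes above the floor were within 2-fold. The early lymphoid, B lineage and NK lists held a larger share 2-fold apart than all genes did, on very few genes each. Of 23 measured early lymphoid genes, 1 was higher, 1 lower and 21 within 2-fold, and the list's median of -0.01 lay at percentile 10.2. After quantile normalization it was -0.02, at percentile 2.25. Of the 17 members above the floor, 12 were lower by some amount and 5 higher, with a median of -0.16 at percentile 4.57, and with no floor the list's median was also -0.16, at percentile 10.12. Dntt, the terminal transferase gene of early lymphoid cells, was 2.43-fold lower at 80.1 against 195. That probe set is of a kind that can match transcripts of other genes. The second Dntt probe set, of a kind that matches several transcripts of the same gene, read 59.2 against 180. Igll1, a surrogate light chain gene, was at least 2.05-fold higher at 126 against 52.6, by a probe set that can match other genes. Its other probe set was below the floor on both arrays. The bright members Ikzf1, the Ikaros gene (5454 against 5150), and Flt3 (1334 against 1390) were within 2-fold. In the B lineage list, 21 of 22 measured genes were within 2-fold, Igll1 being the exception, and 12 were above the floor. In the T lineage list only 7 of 21 measured genes were above the floor and 0 were 2-fold apart. The largest differences there were those of Cd8a (148 against 88.9) and the adaptor gene Lat (1295 against 877). The Cd8a value comes from 1 of 5 probe sets, of a kind that can match other transcripts, with the others below the floor on both arrays. Of the 19 measured genes of the NK and innate lymphoid list, Gzmb and Nkg7 were lower and 17 were within 2-fold. Of the 12 above the floor, 8 were higher by some amount and 4 lower. The NK list's median was 0 with the other members counted at 0, and it was 0.11 (percentile 99.2) with the floor at the 25th percentile, 0.26 (percentile 99.9) with no floor and 0.08 (percentile 94.2) over the members above the floor.

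The stem cell list had 27 of 29 measured genes within 2-fold and a median log2 difference of -0.04, at percentile 16.3. Without probe sets that match several transcripts the median was -0.18, at percentile 0.3, and against unmatched random lists the median of -0.04 lay at percentile 0.88. Slamf1, which encodes the stem cell surface marker CD150, was 2.43-fold higher at 233 against 95.7, by 1 of 3 probe sets, with the others below the floor. Fgd5, a gene active in haematopoietic stem cells, was at least 2.10-fold lower at 61.3 against 129. The abundant members Cd34 (8197 against 8563) and Kit (3388 against 3293) differed by much less. In the list of Hox genes, 18 were measured, 9 were above the floor and 0 were 2-fold apart. Hoxa9 read 3262 against 4612 and Hoxb4 122 against 194.

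The medians of the megakaryocyte and erythroid lists were above those of matched random lists, by amounts under 2-fold. Of 18 megakaryocyte genes, all above the floor, 16 were higher by some amount and 2 lower, and 0 were 2-fold apart. The median log2 difference was 0.25, at percentile 100, and the middle 95% of the random lists reached 0.09. It was 0.14 with the floor at the 75th percentile and 0.17 with the mean over each gene's probe sets, both at percentile 99.99. The chemokine gene Ppbp read 3075 against 1753, the P-selectin gene Selp 1528 against 909, and the platelet factor 4 gene Pf4 21045 against 19179. Of 11 erythroid genes above the floor, 10 were higher by some amount and 1 lower. The members below the floor on both arrays, named after their values were seen, were Hba-a1, Alas2, Car1, Ermap, Slc4a1, Rhag and Sphk1. The median over the 18 measured erythroid genes was 0.13, at percentile 100. It was 0.05 (percentile 99.9) with the mean over each gene's probe sets, 0.25 with the floor at the 25th percentile, and 0, inside the middle 95% of random lists, with the floor at the 75th. Klf1, the erythroid transcription factor gene, read 138 against 87.1. Tspan33 read 502 against 264, while 2 of its other probe sets went the other way.

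**Figure D2:**
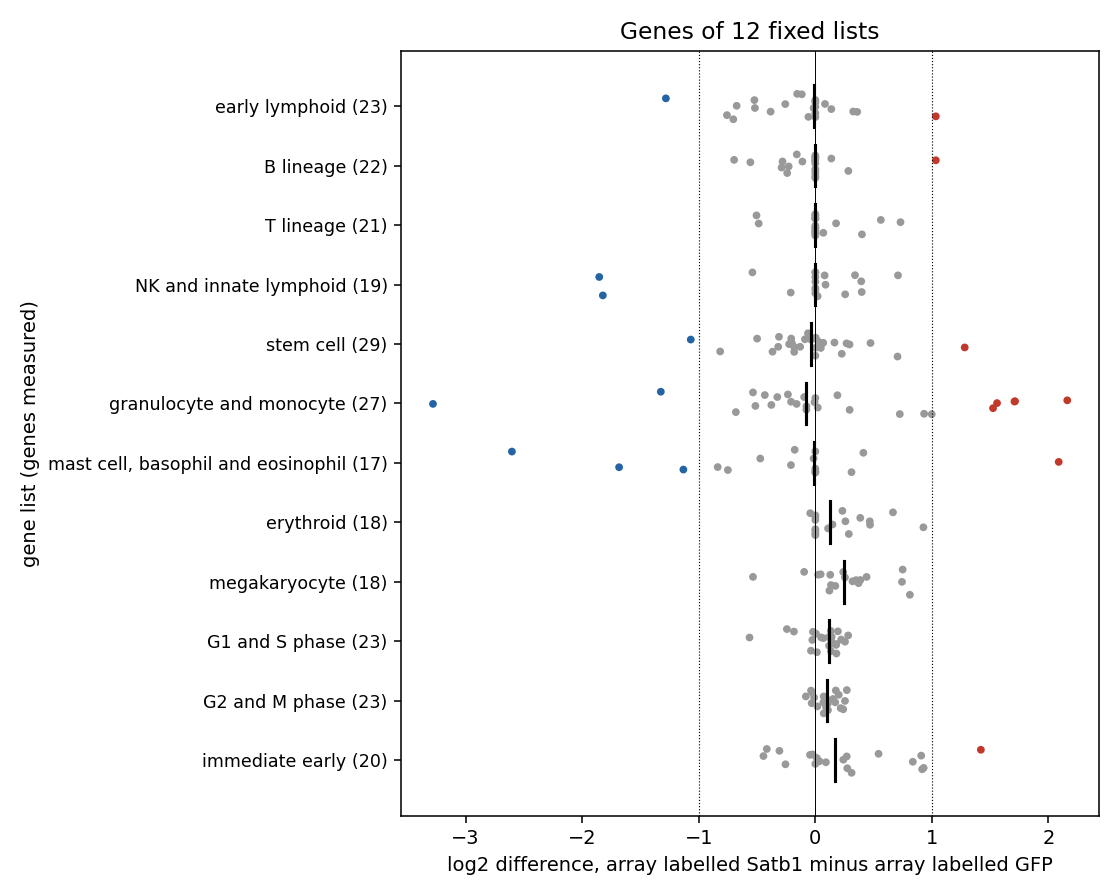
Log2 difference (array labelled Satb1 minus array labelled GFP, x axis) of each measured gene of 12 fixed lists (y axis, number of genes measured in brackets), 1 point per gene, red or blue where at least 2-fold higher or lower (dotted lines). Vertical bars are list medians; the megakaryocyte median was 0.25 and the granulocyte and monocyte genes ran from -3.28 to 2.16.

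Other lists covered the cell cycle, signalling and stress. The immediate early genes had a median log2 difference of 0.17, at percentile 100, with 13 of the 19 above the floor higher by some amount, 6 lower, and Fos alone 2-fold apart. With the floor at the 75th percentile the median was 0, at percentile 50.06, and after quantile normalization it was 0.27. The list of cyclin-dependent kinase inhibitors and quiescence genes had a median of 0.12, at percentile 99.7. It was 0 (percentile 49.4) with the floor at the 75th percentile and 0.20 (percentile 100) with no floor. Its genes Klf4 (324 against 153, 2.12-fold) and Klf2 (265 against 130, 2.05-fold) encode Krüppel-like transcription factors, and the other 14 were within 2-fold. The inhibitor genes, named after their values were seen, went both ways. Cdkn2c (846 against 759) and Cdkn2d (1878 against 1461) were higher, and Cdkn1a (1384 against 1672) and Cdkn1c (53.2 against 72.1) lower. Cdkn1b read 1604 against 1605, and Cdkn2a and Cdkn2b were below the floor on both arrays. The median therefore does not stand for the inhibitors. The G1 and S phase list had a median of 0.12, at percentile 99.5, and the G2 and M phase list a median of 0.10, at percentile 97.3 (98.7 with the mean over each gene's probe sets), with 0 of 23 measured genes 2-fold apart in each. Pcna, the replication clamp gene, read 18656 against 18591, and Mki67, the gene of the proliferation antigen Ki-67, 10514 against 10748. The G1 and S phase list no longer stood apart with the mean over each gene's probe sets (median 0.04, percentile 83.8). The largest difference in it went against the median: the thymidylate synthase gene Tyms read 279 against 412, while another of its probe sets went the other way, at 137 against 104, and Gins2 read 1428 against 1174. In the G2 and M phase list the largest were those of Kif20a (1948 against 1616) and Aurka (2221 against 1862).

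Genes of MHC class I and antigen processing had a median of -0.10, at percentile 1.80, with 10 of 13 lower by some amount and 0 lower by 2-fold. Without probe sets that match several transcripts, the list lay at percentile 7.44, and with the mean over probe sets at 2.63. The peptide transporter gene Tap1 read 1614 against 2149 and the regulator gene Nlrc5 625 against 784. Ribosomal protein genes had a median of -0.11, at percentile 0.02, with 11 of 14 lower by some amount. Rplp0 read 26731 against 31338 and Rpl8 21827 against 24759. After quantile normalization the ribosomal median was -0.04, at percentile 12.7, and without probe sets that match several transcripts -0.10, at percentile 6.67. In the TGF-beta and BMP list (median 0.06, percentile 98.2) the inhibitor gene Id3 was at least 2.35-fold higher, at 145 against 55.0, and the other 18 measured genes were within 2-fold. This list did not stand apart after quantile normalization, at percentile 94.6, nor with the floor at the 25th percentile (95.7) or the 75th (50.2), with no floor (95.67) or with the mean over probe sets (64.1). The cytokine and chemokine receptor list had a median of -0.15, at percentile 5.34. It was -0.24, at percentile 0.31, without probe sets that match several transcripts, and -0.17, at percentile 2.22, over the members above the floor. Against unmatched random lists the -0.15 lay at percentile 0.03. There the neutrophil chemokine receptor gene Cxcr2 was 2.14-fold lower (88.8 against 190) and Il10ra 2.12-fold lower (92.8 against 197). The other Il10ra probe sets were below the floor on both arrays. Among 26 cytokines and chemokines, Tnf was 2.02-fold lower (174 against 351) and the rest were within 2-fold. Cxcr2, Il10ra and Tnf were under 2-fold apart after quantile normalization, with log2 differences of -0.94, -0.93 and -0.89, and so was Fgd5 at -0.93.

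No gene was 2-fold apart in the Wnt, Notch, interferon, p53, unfolded protein and amino acid stress, chromatin regulator, or dendritic cell and macrophage lists. Their medians lay between percentiles 50.9 and 70.2. The dendritic cell and macrophage median was 0, but 0.09 (percentile 98.8) with the floor at the 25th percentile and 0.14 (percentile 99.4) over the 12 members above the floor. The chromatin regulators had a median of 0.01 and a mean of -0.02. Notch1 read 456 against 653, while its other probe set went the other way, at 149 against 90.8, and Jag2 read 130 against 183. In the stress list Atf3 read 144 against 76.3 and Ern1 1279 against 2011, with another Ern1 probe set the other way at 133 against 120. Of the p53 targets, Perp read 1720 against 983 and Zmat3 237.3 against 392.5. The interferon genes Bst2 and Rsad2 read 1107 against 1564 and 187 against 255, with 2 other Rsad2 probe sets the other way. The Wnt genes Sfrp1 and Fzd4 read 103 against 134 and 79.5 against 61.0, the chromatin genes Cbx7 and Hdac9 146 against 90.0 and 172 against 272, and Cd86 and Ctss of the dendritic cell and macrophage list 78.7 against 32.0 and 1685 against 1342. Of 18 stromal and fibroblast genes, 5 were above the floor and 0 were 2-fold apart, with Thy1 at 84.7 against 120 and Acta2 at 86.7 against 122. Of 14 endothelial genes, 9 were above it and 0 were 2-fold apart, with Kdr at 107 against an intensity below the floor and Tie1 at 180 against 133. The endothelial median was 0.0026, at percentile 98.6, and at percentile 81.1 over the members above the floor. The medians of the B lineage, T lineage, NK and innate lymphoid, Hox, cytokine and chemokine, and stromal lists were 0, none above percentile 51.4 or below percentile 50. Members below the floor count as 0 and largely fix these medians. Over members above the floor the medians were -0.19 for the B lineage (percentile 3.73), 0.18 for the T lineage (95.8), -0.12 for Hox genes (37.9), -0.15 for cytokines and chemokines (11.5) and -0.36 for the stromal list (2.53). The housekeeping list had a median of 0.02, at percentile 44.6, with Tfrc at 5408 against 4523 and Ywhaz at 14546 against 12278, where 3 of the other Ywhaz probe sets went the other way. The Y-linked genes Eif2s3y (2942 against 3116) and Kdm5d (848 against 941) were bright on both arrays, and Xist, named after its values were seen, was below the floor on both, at 38.5 and 58.8. The sex-linked list had a median of -0.04, at percentile 32.3.

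Of the 30 lists, 9 lay outside the middle 95% of matched random lists, 7 of them higher and 2 lower. Nominally 1.5 would be so with independent genes and no difference. That figure takes every list as free to fall outside, while members below the floor held several medians at 0. The endothelial list, 1 of the 7, had a median of only 0.0026. Genes of a list are co-regulated and share an array, so the count of 9 describes the 2 arrays and is not a test of the transduction.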

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

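With 1 array per group there was nothing to leave out, and no paired analysis was possible because each group holds 1 array, so the groups share fewer than 2 replicate numbers. The counts of genes 2-fold apart (30 higher, 95 lower on the array labelled Satb1) kept their order, lower above higher, under every alternative run, but their size followed the floor. Higher and lower counts were 54 and 60 with quantile normalization, 440 and 787 with the floor at the 25th percentile, 5 and 18 with the floor at the 75th percentile, 1478 and 1979 with no floor, 407 and 653 with a pseudocount, 18 and 57 with the mean over probe sets, 9 and 10 at 3-fold, 193 and 432 at 1.5-fold, and 7 and 20 at a mean intensity of at least 500, the last chosen after seeing the data. With no floor, genes below 61.7 enter. The within-gene SD of 0.35 at intensities under 200 was taken from probe sets above the floor on both arrays. It therefore does not measure the spread of the genes that enter. Median centring moved the median by 0.03 and gave counts within 1.5 times. None of the named genes 2-fold apart changed sign under the alternatives run, although many came under 2-fold or to 0. This was not limited to dim genes or conflicting probe sets. With the floor at the 75th percentile, an intensity of 443, Camp and Prg2 came under 2-fold, at 834 and 825 on the array labelled Satb1.

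The megakaryocyte list stood apart under every alternative. Medians of other lists that stood apart came inside the middle 95% of random lists as follows. With the floor at the 75th percentile, the erythroid, quiescence, immediate early, TGF-beta and BMP, and endothelial medians were 0. With the mean over probe sets, the medians were 0.0445 (G1 and S phase), -0.0927 (MHC class I), 0 (TGF-beta and BMP) and 0 (endothelial). Without probe sets that match several transcripts, they were -0.1002 (MHC class I, at percentile 7.44), 0 (endothelial) and -0.0955 (ribosomal proteins). With quantile normalization, they were 0.051 (TGF-beta and BMP), 0.0193 (endothelial) and -0.0358 (ribosomal proteins). The TGF-beta and BMP median was also inside at 0.0819 with the floor at the 25th percentile, with no floor, with a pseudocount (0.081) and over members above the floor (0.0819), and at 0.0299 with agreeing probe sets. The endothelial median was inside at 0.0266 with the floor at the 25th percentile or no floor, 0.0241 with a pseudocount, 0 with agreeing probe sets, 0.0026 against unmatched lists and 0.0256 over members above the floor. In 19 further comparisons of a list and an alternative, a median that had not stood apart came to lie outside the middle 95%. Lower medians were those of the stem cell list (-0.1813) and cytokine and chemokine receptors (-0.24) without probe sets that match several transcripts, early lymphoid genes with quantile normalization (-0.0221), the mast cell, basophil and eosinophil list with the floor at the 25th percentile (-0.1771) or over members above the floor (-0.3408), and the receptors over members above the floor (-0.1741). Higher medians were those of the NK and innate lymphoid list with the floor at the 25th percentile (0.1132), no floor (0.2558) or a pseudocount (0.2542), the dendritic cell and macrophage list with the floor at the 25th percentile (0.0877) or over members above the floor (0.1446), and the G2 and M phase list with the mean over probe sets or over members above the floor (both 0.096). Against unmatched lists the stem cell, granulocyte and monocyte, and receptor medians came outside on the low side, and the G2 and M phase, unfolded protein and amino acid stress, and chromatin regulator medians on the high side. The cause was not tested beyond these settings.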

Other observations

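The tests on the Satb1 probe sets, on bright genes after quantile normalization and on histone genes were chosen only after the values were seen; the tests of neutrophil markers, basophil markers and the direction split were fixed before their results. The value of Gata2, 1 of the basophil markers, had been seen in the stem cell list by then. Among the 6623 genes with a mean intensity of at least 500, where the spread between probe sets is smallest, 7 were at least 2-fold higher and 20 lower on the array labelled Satb1. The higher ones were Camp, Prg2, S100a8, Lcn2, S100a9, Fos and Tgfbi, a TGF-beta-induced matrix protein gene, at 947 against 402. Some genes reached this mean only through the array where they were high. Camp, Prg2, Lcn2 and Tgfbi were under 500 on the array labelled GFP (186.5, 194.0, 381.4 and 402). Some of the lower genes, such as Ms4a3 (268.6), were under 500 on the array labelled Satb1. The small spread need not hold for such genes. The lower ones included Slpi, a leukocyte protease inhibitor, at 1137 against 3056, Hk3, a myeloid hexokinase, at 2098 against 4399, Cybb, the large subunit of the phagocyte oxidase, at 579 against 1224, and the acute-phase gene Saa3 at 345 against 701. H2-Ob, a chain of the class II modulator DO, read 501 against 1171, the lectin gene Clec2d 897 against 1894 and the glycosyltransferase gene B3gnt5 545 against 1201. The nuclear RNA Malat1 read 2500 against 5012. Of 6 clustered histone genes above the floor, 3 were lower and 3 higher: H3c4 and H3c7 (219 against 504) were 2-fold lower, while H1f2 read 2595 against 1745.

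The transduced gene itself was not higher on the array labelled Satb1. If the 2 labels had been exchanged, the over-expressed transcript would be higher on the array labelled GFP by 2-fold or more, where a probe set lies in the transduced sequence. The brightest Satb1 probe set differed by -0.30 on the log2 scale, under that bound, but probe sets outside the transduced sequence would miss the transgene under either labelling, so this does not decide. The probe sets above the floor differed from each other by up to 0.72, and without their places in the transcript a transgene that lacks their targets stays a candidate explanation. The position of the probe sets against the insert is what a check would need.

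Camp, Ltf, Lcn2, S100a8 and S100a9, genes that neutrophils express, were 2-fold higher, while Ms4a3 and the basophil and mast cell genes Fcer1a, Mcpt8 and Ms4a2 were 2-fold lower. These genes were picked by their values. They do not stand for the granulocyte and monocyte list, which had 11 genes higher and 15 lower by some amount. The mast cell, basophil and eosinophil list had a median of -0.01 with members below the floor counted at 0. Of its 12 members above the floor, which include the genes picked, 9 were lower and 3 higher, Prg2 among these. Their median was -0.34, at percentile 0.03. Mature neutrophils carried over into one preparation may raise genes such as Camp and S100a8, and would raise other neutrophil markers too. The 17 markers above the floor that were fixed for this had a median log2 difference of 0.12 (bootstrap interval over genes -0.26 to 0.30), with 9 higher and 8 lower. This was below the 0.5 asked of carry-over and not under the 0.1 that would have spoken against it, so carry-over stays open. Several of these markers were already bright on the array labelled GFP, such as Slc2a3 (5767) and Anxa1 (4192), named after their values were seen. A small carry-over would move such markers little. Cd177, Fcgr4, Itgb2l, Mgam and Stfa2l1, also fixed for this, were below the floor on both arrays and were left out. The receptor genes Csf3r and Cxcr2 were lower. Fewer cells of the basophil and mast cell lineage would lower further markers of it, yet the 18 above the floor had a median of -0.058 (interval -0.35 to 0.16), which is above the -0.1 that would have spoken against this, but with an interval that reaches past that bound, so it stays open, and several of these genes are also expressed by other progenitors. An effect of the Satb1 transduction cannot be told apart from a difference between 2 single preparations.

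More genes were 2-fold lower than higher on the array labelled Satb1 (95 against 30). A difference in the distribution of signals between the arrays may account for this. After quantile normalization 52.6% of the genes 2-fold apart were lower (exact 95% binomial interval 43.1% to 62.1%). The percentage lay inside the range fixed for this explanation, but the interval reached past the upper end of that range, so this stays open. Quantile normalization would also level a real net decrease. Dim genes near the floor as the only source were not decided by the bright genes. Of these, 74.1% were lower (interval 53.7% to 88.9%). The percentage passed the bound fixed as speaking against this explanation, but the interval reaches below that bound. Among bright genes after quantile normalization 17 of 24 were lower, or 70.8%, with an interval of 48.9% to 87.4% that includes an equal split, so whether an imbalance remains among them is not shown. These intervals treat genes as independent, which genes sharing an array are not, and are therefore too narrow.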
